A study of Mus musculus with 4 samples.

How the data were processed

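Total RNA from mouse ST2 bone marrow stromal cells was hybridised to Affymetrix Mouse Genome 430 2.0 arrays, 1 array per group. Per the labels' protocols, cells were grown with 10% serum under 5% CO2, RNA was isolated with on-column DNase treatment, and samples needed an RNA integrity number above 9.5. Per the labels' protocols, labelled cRNA was made from 500 ng of RNA with a kit that primes from the poly-A tail, so the signal of a probe set comes mostly from the 3' end of its transcript.

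The authors deposited 1 value per probe set and array, on a log2 scale, already on a common scale between arrays. The log base was not stated and was taken from the range of the values, which ran from 1.53 to 14.5 on the control array. The method that summarised the probes and scaled the arrays is not given in the sources used here, and no detection calls were used. A ratio that compresses or expands under that method would carry over into each fold change given here.

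Each array held 45101 probe sets, of which 64 were control probe sets. The platform annotation used here gave 34958 probe sets 1 gene symbol and 932 several symbols, and it did not list 9211. Symbols were updated through the Entrez gene number, which matched for 34754 probe sets. Probe sets with several symbols or none were left out of gene counts, and the brightest probe set on average stood for each of 18193 genes. The reference table was used for names and gene spans only, and no positions are given because the build behind the probe sets was not used here.

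Values under the median of all values, log2 5.23, were raised to that floor. A gene entered a comparison when at least 1 of the 2 arrays was above the floor, and 11685 genes were above it on at least 1 of the 4 arrays. Where the dimmer array lay at or under the floor, the ratio is a lower bound and is written as at least a given fold. Where both arrays lay under the floor, no ratio was computed.

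Comparisons were each LIPUS array minus the control array, and each LIPUS array minus the preceding one. With 1 array per group there was no test, no p-value and no standard error. A gene was counted as changed by a fixed rule of size, a difference of at least 1 on the log2 scale, which is 2-fold. The words rose and fell are used for genes past that rule.

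Technical error was described by the difference in log2 ratio between 2 probe sets of one gene, divided by the square root of 2. Unchanged arrays were simulated 100 times with that noise, pooled over the LIPUS times, around each gene's mean and against the same control array. They give the counts, overlaps and correlations that arise from that technical noise alone. Because of the pooling, the simulated noise is below that measured at 1 h. The simulation leaves out the spread between cultures, which was not measured, so it is too low a benchmark for unchanged cells. The rule of size was tested on simulated data for the 0.5 h comparison with 11473 genes. It recovered 50 of 50 genes raised by 1.5 on the log2 scale, 47 of 50 raised by 1.2, and 50 of 50 lowered by either amount, and it called 0 of 11273 unchanged genes. The changed genes had means more than 1.5 above the floor, and the noise put in had an SD of 0.12. The result checks the calculation and says nothing about genes near the floor or noisier arrays.

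Before the data were examined, 36 gene lists were fixed. For each list, the median log2 ratio of its measured members was placed among the medians of 10000 random lists of the same size, matched on mean expression in 20 bins. The percentile describes these arrays and is not a test of the treatment. Lists with under 5 measured members were given no percentile.

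The genes named in the text were also set by a rule fixed before the data were examined. For each time the rule took the 10 highest and 10 lowest ratios of at least 2-fold with both arrays above the floor, and the 5 brightest genes past 2-fold whose dimmer array was at or under the floor. It also took every member of a fixed list past 2-fold, of which up to 4 per list are given as examples, and a panel of 24 genes at all times, of which 23 had a probe set with 1 symbol. The rule named 41 genes. Every other gene named in the text, including list members short of 2-fold that are not in the panel, was chosen after its values were seen.

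Alternatives covered the floor (25th or 75th percentile, or none), the scaling (median centring, quantile normalization, cyclic loess), the choice of probe sets, the fold threshold (1.5 or 3), both arrays above the floor, and another reference array. The calculations used Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3, and R 4.3.3 with limma 3.58.1 for the quantile and loess scaling.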

Results

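Gene expression was measured in ST2 cells, an established line of fibroblast-like stromal cells from BALB/c mouse bone marrow, with and without low-intensity pulsed ultrasound (LIPUS), a mechanical stimulus used to promote fracture healing. The design asked which transcripts differ from untreated cells during the first hours after a single exposure. One array held control cells kept at 37 °C. The other 3 arrays held cells exposed for 20 min at an intensity of 25 mW per square cm and then cultured for 0.5, 1 or 3 h. The labels do not state whether control cells were handled without ultrasound alongside the others, or when they were harvested.

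The 4 arrays had closely similar distributions of signal. The median log2 signal was 5.23 in the control, 5.21 at 0.5 h, 5.21 at 1 h and 5.25 at 3 h, and 22578, 22468, 22453 and 22703 probe sets lay above the floor in that order. Pearson's r across probe sets, which are not independent replicates, ran from 0.996 to 0.997 between pairs of arrays. There are no replicate arrays, so the number of arrays limits the precision of every value, and differences between cultures of one group were not measured. The only error that could be estimated was between 2 probe sets of one gene, with an SD of the log2 ratio of 0.106 at 0.5 h over 5091 genes, 0.157 at 1 h over 5072 genes and 0.137 at 3 h over 5105 genes.

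At 0.5 h after LIPUS, the highest ratios belonged to genes of inducible chaperones and immediate-early transcription factors, followed by Rsrp1, of neither class, at 4.42-fold. Hspa1a, an inducible chaperone gene, was at least 52.3-fold higher than in the control, where its signal lay under the floor, and its near-identical neighbour Hspa1b rose 11.2-fold. Among immediate-early genes, Fos was at least 12.1-fold higher, Egr1 rose 8.93-fold and Atf3 rose 3.64-fold. In all, 16 of 11574 genes rose at least 2-fold and 0 fell. Simulated unchanged arrays, which hold the noise between probe sets but no spread between cultures, gave at most 1 gene higher by the same rule. With the floor at the 75th percentile, 11 genes were higher: Atf3, Dnaja4 and Edn1 then had only lower bounds, of 0.60, 0.84 and 0.73 on the log2 scale, and Arc and, chosen after its values were seen, Ccdc117 lay under that floor on both arrays.

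Heat shock proteins had the highest median of the fixed lists at 0.5 h, among lists with at least 5 measured members. Of 17 measured members, 5 rose at least 2-fold and 12 did not pass the rule, and the list median was 0.23 on the log2 scale, at the 100th percentile of matched random lists. Besides Hspa1a and Hspa1b, the members that rose were Dnajb1, a co-chaperone, by 5.50-fold, Bag3, another co-chaperone, by 2.18-fold, and Hsph1, a nucleotide exchange factor for these chaperones, by 2.07-fold. Dnaja4, a related co-chaperone outside the list, rose 3.40-fold. Among members chosen after their values were seen, the small heat shock protein genes Cryab and Hspb1 had log2 ratios of 0.78 and 0.59, and the constitutive chaperone genes Hspa8 and Hsp90aa1 had log2 ratios of 0.12 and 0.15. Hspa1a and Hspa1b encode nearly the same transcript, so their probe sets can share signal and the split between them is uncertain. All 3 probe sets assigned to Hspa1b were higher, the other 2 by 3.50 and 3.71 on the log2 scale.

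Of 30 measured immediate-early transcription factors, 3 rose at least 2-fold at 0.5 h and 27 did not pass the rule, with a list median of 0.10 at the 99.97th percentile. Jun, Egr2, Ier2 and Btg2 had log2 ratios of 0.95, 0.89, 0.75 and 0.67, whereas Junb was at 0.12, Myc at 0.17, Klf4 at −0.07 and Nr4a1 at −0.03. Fosb lay under the floor on all 4 arrays. Among 15 regulators that act as feedback on MAP kinase signalling, Phlda1 rose 3.10-fold and the phosphatase gene Dusp1 had a log2 ratio of 0.98. The activity-regulated gene Arc rose 3.49-fold.

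Among secreted and inflammatory genes, Edn1, which encodes the vasoactive peptide endothelin, rose 2.66-fold, and Ptgs2, which encodes an inducible prostaglandin synthase, rose 2.29-fold. Each was the 1 member of its list to pass the rule, with 13 early secreted factors and 15 NF-kB and inflammatory genes measured. The median of the NF-kB list was 0.09, at the 98.0th percentile, and that of the early secreted factors was −0.08, at the 1.09th percentile, with 5 of 13 members above 0. The chemokine gene Cxcl1 was at −0.09, and Il6 lay under the floor. Rsrp1, which encodes an arginine- and serine-rich protein, rose 4.42-fold, and Clk1, which encodes a kinase of splicing factors, rose 2.44-fold. Hmox1, an oxidative stress gene, had a log2 ratio of 0.60. Cholesterol synthesis genes had a median of 0.18 at the 100th percentile, with 13 of 13 members above 0 and none past 2-fold, and TGF-beta target genes had a median of −0.11 at the 0.07th percentile. On this array the probe sets for 18S ribosomal RNA had a median log2 ratio of 0.96 and those for bacterial poly-A control transcripts −0.05. The log2 signal of the 5' minus the 3' probe set, a sign of RNA or cRNA integrity, differed from the control by −0.06 for Gapdh, −0.03 for Actb, −0.09 for Pcx and −0.41 for Tfrc.

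**Figure D1:**
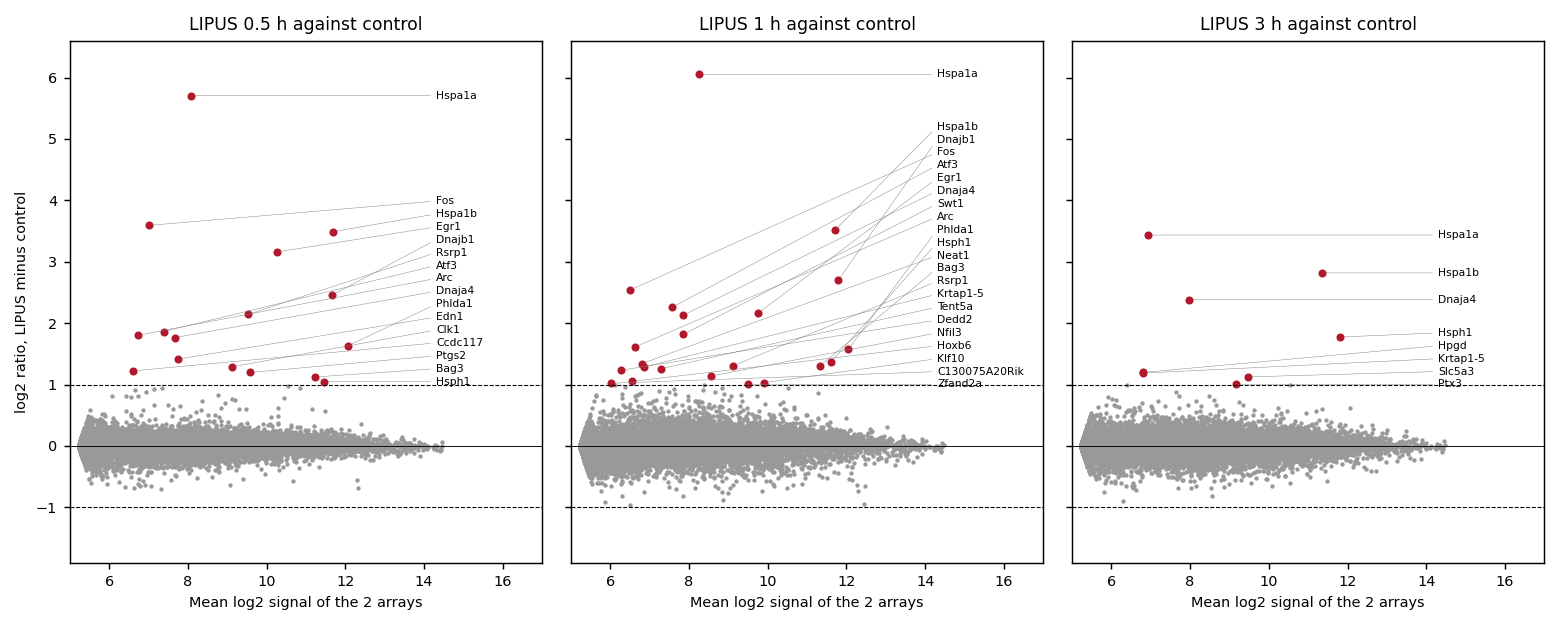
Each point is a gene, with the mean log2 signal of the LIPUS and control arrays on the horizontal axis and the log2 ratio of LIPUS minus control on the vertical axis, for 0.5, 1 and 3 h. Dashed lines mark 2-fold, and the labelled red points are the 16, 22 and 8 genes past it, all of them above 0.

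At 1 h after LIPUS, the chaperone genes and the early transcription factor genes Fos, Egr1 and Atf3 were still past 2-fold. Hspa1a was at least 66.3-fold higher than in the control, Hspa1b rose 11.4-fold and Dnajb1 rose 6.50-fold. Atf3 rose 4.79-fold and Egr1 4.47-fold, and Fos was at least 5.80-fold higher. In all, 22 of 11497 genes rose at least 2-fold and 0 fell. Simulated unchanged arrays gave at most 1 gene higher. The count depends on the floor and on the reference, with 13 genes higher when the floor was set at the 75th percentile and 9 genes higher against the mean of the other 3 arrays. With that floor, Atf3 was at least at 0.99 and Fos at least at 0.05 on the log2 scale, and Arc and Neat1 were among the genes with both arrays under it.

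Of 17 heat shock proteins, 5 rose at least 2-fold at 1 h and 12 did not pass the rule, with a list median of 0.45 at the 100th percentile. These were the same members as at 0.5 h, with Hsph1 up 2.59-fold and Bag3 up 2.47-fold, and Dnaja4 outside the list rose 4.38-fold. Of 30 immediate-early factors, 4 rose and 26 did not pass the rule, with a median of 0.34 at the 100th percentile. The fourth was Klf10, a zinc finger transcription factor, which rose 2.04-fold after a log2 ratio of 0.08 at 0.5 h and lay just under the rule with each other scaling, for example at 0.99 after centring. Junb, at a log2 ratio of 0.88, and Btg2, at 0.89, were short of the rule. Phlda1 rose 2.97-fold and Arc rose 3.06-fold. Nfil3, a transcriptional repressor that acts in the circadian clock, rose 2.20-fold as the 1 member of 16 measured clock genes past the rule. Swt1, which encodes a nuclear RNA endonuclease, rose 3.52-fold. The long noncoding RNA Neat1, a scaffold of nuclear paraspeckles, rose 2.53-fold by its brightest probe set, while its other measured probe set had a log2 ratio of −0.18. Rsrp1 and Krtap1-5, which the rule named at other times, had log2 ratios of 1.30 and 1.28. Among genes chosen after their values were seen, Tent5a had a log2 ratio of 1.26, Dedd2 1.23, Hoxb6 1.05, C130075A20Rik 1.02 and Zfand2a 1.00.

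Several lists with no member past 2-fold had displaced medians at 1 h, and their example members, other than Pparg, were chosen after their values were seen. Cholesterol synthesis genes had a median log2 ratio of 0.34, at the 100th percentile, with 12 of 13 measured members above 0, among them Mvd at 0.44 and Fdft1 at 0.37. BMP target genes had a median of 0.26, also at the 100th percentile, with 12 of 13 members above 0, among them Id3 at 0.50, Id1 at 0.46 and Id2 at 0.44. Adipocyte genes had a median of 0.24 at the 99.8th percentile, with Cebpb at 0.60 and Pparg at 0.24. The NF-kB list and the p53 list each had a median of 0.16 at the 99.1st percentile, with Trp53inp1 at 0.81 in the latter. G2/M cell cycle genes had a median of −0.10 at the 0.05th percentile, and actin cytoskeleton genes had a median of −0.05 at the 0.45th percentile. TGF-beta target genes had a median of −0.12 at the 0.25th percentile, but their mean was 0.01 and the median was 0.03 with the floor at the 75th percentile. Probe sets for bacterial poly-A control transcripts had a median log2 ratio of 0.28 on the same array, with 12 of 12 higher than on the control array, and those for 18S ribosomal RNA had a median of 1.91. The 5' minus 3' difference relative to the control was −0.16 for Gapdh, −0.13 for Actb, −0.23 for Pcx and −0.30 for Tfrc.

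At 3 h after LIPUS, 8 genes were past 2-fold, of which 4 encode chaperones or their partners. Hspa1a was at least 10.8-fold higher than in the control, Hspa1b rose 7.05-fold, Dnaja4 rose 5.22-fold and Hsph1 rose 3.42-fold. The other 4 genes were Hpgd, which encodes a prostaglandin-degrading enzyme, at 2.29-fold, Krtap1-5, a keratin-associated protein gene, at 2.27-fold, Slc5a3, a myo-inositol transporter gene, at 2.18-fold, and Ptx3, which encodes a secreted pentraxin, at 2.00-fold. In all, 8 of 11574 genes rose at least 2-fold and 0 fell, against at most 1 higher in simulated unchanged arrays. The other measured probe set of Slc5a3 had a log2 ratio of 0.53, and the mean over both was 0.83, short of the rule. Hpgd and Ptx3 each rest on a single probe set, since their other probe sets lay under the floor on every array. Ptx3 lay at the rule, with a log2 ratio of 1.00. With the floor at the 75th percentile, 5 genes were higher, Hspa1a had a lower bound of 0.95 on the log2 scale, and Hpgd and Krtap1-5 lay under that floor on both arrays, and against the mean of the other 3 arrays 1 gene was higher.

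Of 17 heat shock proteins, 3 were past 2-fold at 3 h and 14 were not, with a list median of 0.41 at the 100th percentile. Dnajb1 was at a log2 ratio of 0.26 by its brightest probe set, although its other probe set had a log2 signal of 10.31 in the control and 11.09 at 3 h. Bag3 was at 0.54 and, chosen after their values were seen, Cryab was at 0.99 and Hspb1 at 0.82. None of the 30 immediate-early factors was past 2-fold, and their median was 0.04 at the 80.2nd percentile. Fos was at a log2 ratio of at least 0.47, Egr1 at 0.16, Jun at −0.01, Atf3 at −0.42 and Nr4a1 at −0.52. Ptgs2 was at −0.20 and Cxcl1 at −0.04.

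Lists without a 2-fold member were again displaced at 3 h in both directions, with example members chosen after their values were seen. Genes for the haematopoietic niche and osteoclast support had a median of 0.24 at the 100th percentile, with 7 of 11 members above 0. Among them Kitl, which encodes stem cell factor, was at 0.61 and Angpt1, which encodes angiopoietin, at 0.46, while Csf1 was at −0.33 and Lepr at −0.16. Cholesterol synthesis genes had a median of 0.19 at the 99.98th percentile. TGF-beta target genes had a median of −0.22 at the lowest percentile, 0, with Skil at −0.49 and Tgfb1i1 at −0.46. Clock genes had a median of −0.17 at the 0.015th percentile, G2/M genes −0.12 at the 0.02nd, glucocorticoid response genes −0.14 at the 0.835th and actin cytoskeleton genes −0.05 at the 0.965th. Probe sets for the poly-A control transcripts had a median log2 ratio of 0.41 on this array, with 12 of 12 higher than on the control array, and those for 18S ribosomal RNA had a median of 1.79. The 5' minus 3' difference relative to the control was −0.16 for Gapdh, −0.09 for Actb, −0.22 for Pcx and −0.14 for Tfrc.

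Over the 3 h, 29 genes rose at least 2-fold at 1 or more times. The ratio was highest at 0.5 h for 9 genes, including Fos, Egr1, Ptgs2, Edn1 and Clk1, at 1 h for 15 genes, including Hspa1a, Dnajb1, Atf3 and Klf10, and at 3 h for 5 genes, namely Dnaja4, Hsph1, Hpgd, Slc5a3 and Ptx3. Of the 3 probe sets of Dnaja4, 1 was instead highest at 1 h, with log2 signals of 8.22, 8.86 and 8.25 at 0.5, 1 and 3 h. At 3 h, by the brightest probe sets and with dim values raised to the floor, 20 of the 29 genes lay within 1.5-fold of the control. Of the rest, 8 were past 2-fold, and 1 lay between. The 20 include Fos, whose log2 ratio of 0.47 is only a lower bound, so it may lie outside 1.5-fold. They also include Dnajb1, whose other probe set had log2 signals of 10.31 in the control and 11.09 at 3 h, more than 1.5-fold apart. Of the 8, Hpgd, Slc5a3 and Ptx3 were short of 2-fold at 0.5 h and 1 h. Hspa1a, Hspa1b, Dnaja4 and Hsph1 were past 2-fold at all 3 times. By the same condition, these 4 were the genes for which the control array lay at least 2-fold below each of the LIPUS arrays. Fos was at least 2-fold higher at 0.5 h than on every other array, Swt1 was so at 1 h, and 0 genes were at 3 h.

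**Figure D2:**
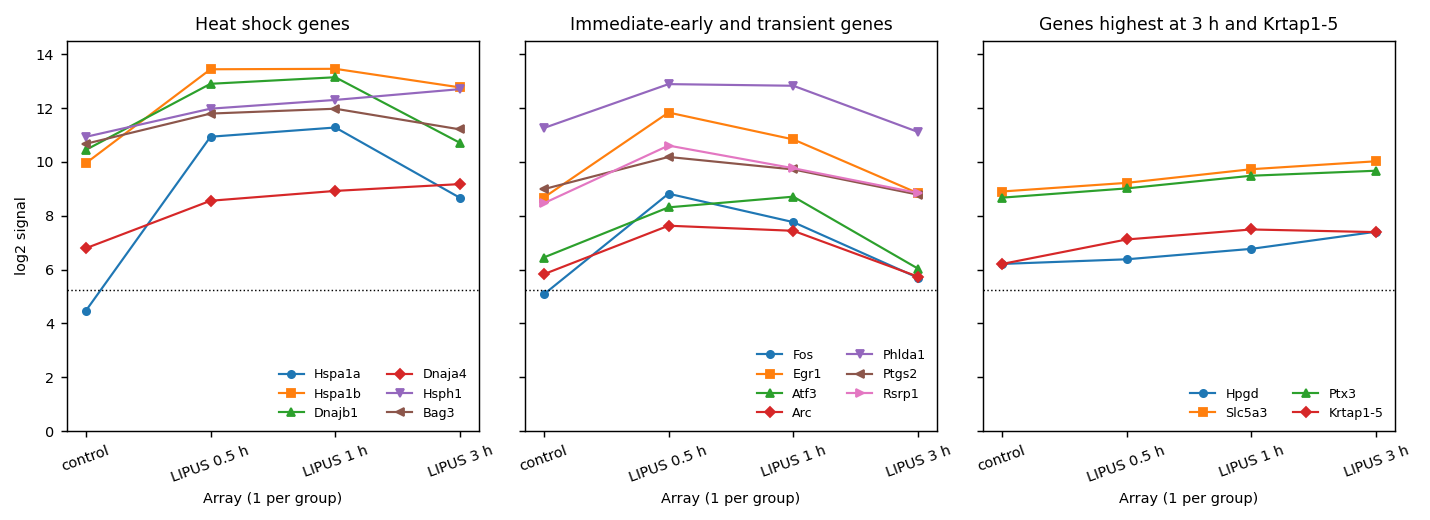
Log2 signal (vertical axis) on each of the 4 arrays (horizontal axis) for heat shock genes, immediate-early and other transient genes, and genes highest at 3 h with Krtap1-5, where each line is a gene and the dotted line is the floor. Hspa1a starts under the floor at 4.46, Fos and Egr1 peak at 0.5 h, and Dnaja4 and Hsph1, by their brightest probe sets, are highest at 3 h.

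Steps between adjacent times did not use the control array. From 0.5 h to 1 h, Fos fell by 1.06 on the log2 scale, and 4 genes rose, which were Swt1 by 1.38, Phxr4 by 1.27, C130075A20Rik by 1.02 and D130051D11Rik by 1.01, the last 3 chosen after their values were seen. From 1 h to 3 h, 0 genes rose and 10 fell at least 2-fold. The falls on the log2 scale were −2.68 for Atf3, −2.62 for Hspa1a, −2.44 for Dnajb1, −2.07 for Fos, −2.00 for Egr1, −1.72 for Phlda1, −1.70 for Arc and −1.36 for Swt1. The fall of Dnajb1 rests on its brightest probe set, and the other had log2 signals of 12.02 at 1 h and 11.09 at 3 h, less than 2-fold apart. Dedd2 at −1.32 and Dlx2 at −1.04, both chosen after their values were seen, complete the 10.

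The genes past 2-fold were shared between times. The 0.5 h and 1 h comparisons shared 12 genes, where independent lists would share 0.0307, the 0.5 h and 3 h comparisons shared 4 against 0.0111, and the 1 h and 3 h comparisons shared 5 against 0.0154. Simulated unchanged arrays against the same control shared 0. The correlation of log2 ratios across genes was 0.67 for 0.5 h with 1 h, 0.49 for 0.5 h with 3 h and 0.69 for 1 h with 3 h, and simulated unchanged arrays gave 0.50 for each pair. The covariances were 0.0243, 0.0146 and 0.0273, against 0.00954, 0.00954 and 0.00955 in simulation. Part of any excess may come from the 1 shared control array. Of the 3 pairs of contrasts that share no array, 1 h minus 0.5 h with 3 h minus control had an r across genes of 0.432 and a covariance of 0.0125. For 3 h minus 0.5 h with 1 h minus control r was 0.0800 and the covariance 0.00300, and for 1 h minus 3 h with 0.5 h minus control r was 0.364 and the covariance 0.00948.

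No measured member of the fixed osteoblast, adipocyte, chondrocyte, stromal identity, YAP/TEAD, actin cytoskeleton or adhesion lists passed the 2-fold rule at any time. Of 9 measured osteoblast genes, 0 passed the rule, and the medians were 0.00, −0.07 and 0.03 at 0.5, 1 and 3 h, with Alpl and Bmp2 under the floor on all arrays. The fixed list held 19 genes. Runx2 was the panel gene without a probe set of 1 symbol, so it has no value here. Pparg, the regulator of adipocyte differentiation, was at 0.12, 0.24 and 0.15. YAP/TEAD target genes had medians of −0.04, −0.00 and 0.04, and the matricellular genes Ccn1 and Ccn2 were at 0.36 and −0.17 at 0.5 h. Other probe sets of Ccn1 disagreed on its size and course. Log2 signals in the control, at 0.5 h and at 1 h were 7.18, 7.87 and 7.98 for a dim probe set. They were 6.92, 7.51 and 7.76 for another dim one, and 12.03, 12.39 and 11.95 for a bright one. Housekeeping genes had medians of −0.00, 0.02 and 0.02. Unfolded protein response genes had medians of 0.03, 0.04 and −0.07, and NRF2 and metal response genes had medians of 0.04, 0.09 and −0.08, with 0 members past 2-fold in either.

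Markers of other cell types were mostly under the floor. Of the fixed markers, 3 macrophage, 4 lymphocyte, 3 epithelial, 1 erythroid and 1 granulocyte genes were measured at each time, with 3, 3 and 2 endothelial genes at 0.5, 1 and 3 h, and 0 were past 2-fold. Over the 36 lists, 90 percentiles were computed, of which 13 lay above the 99th and 9 under the 1st, where 0.9 on each side would arise by chance among independent lists. These percentiles are not independent, since the 3 times share 1 control array and some lists share members. The random lists also drew each gene separately. The 0.9 is therefore no benchmark for lists whose genes may vary together.

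**Figure D3:**
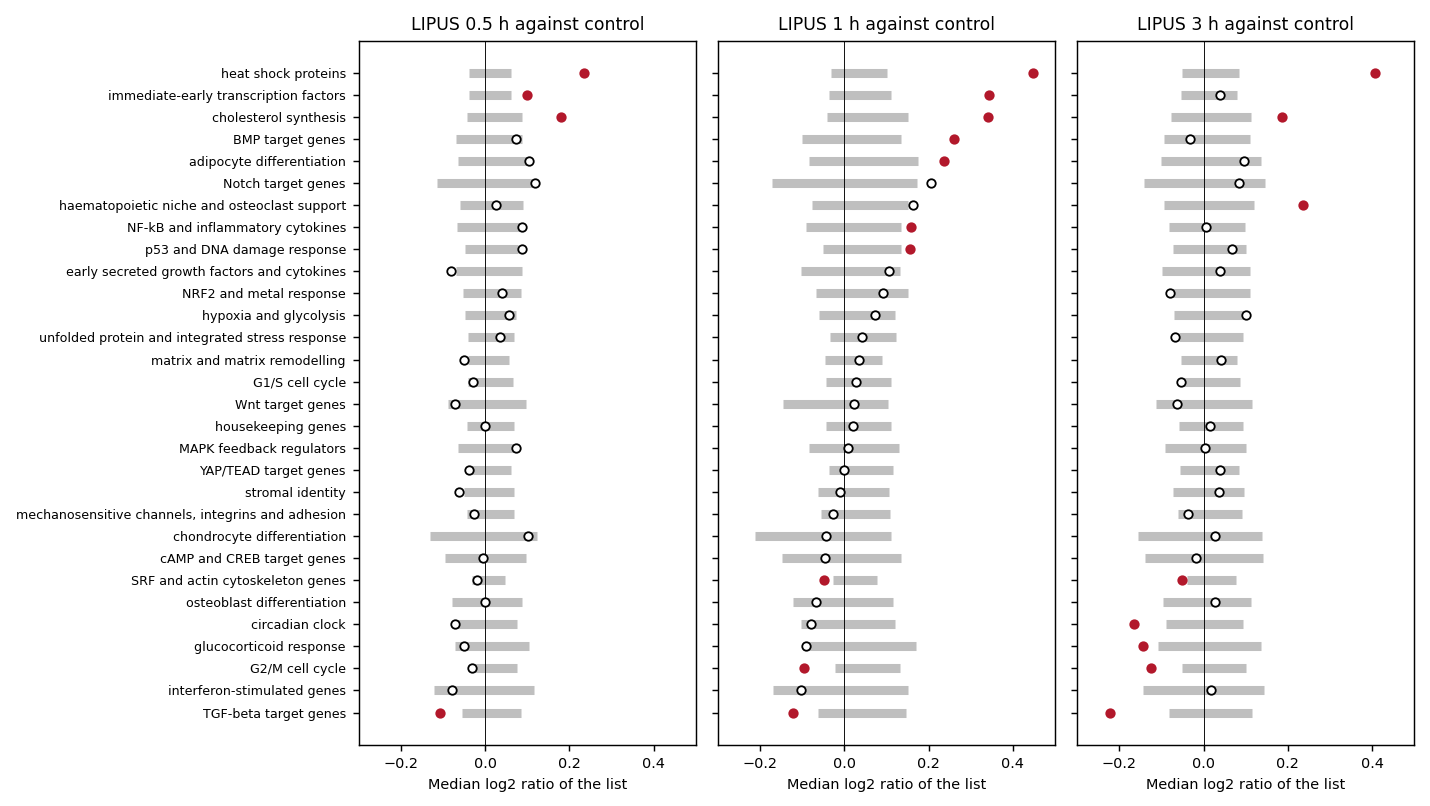
Median log2 ratio of each fixed gene list with at least 5 measured members (horizontal axis, points) against the control at 0.5, 1 and 3 h, with grey bars spanning the central 95% of 10000 matched random lists. Red points lie above the 99th or under the 1st percentile, and heat shock proteins lie farthest to the right at 0.23, 0.45 and 0.41.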

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

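Each pattern weighed was first noticed in these data. The comparison of the heat shock list with random lists was chosen as a test of scaling after its result had been seen. The comparison of probe sets within a gene was added after the correlation between disjoint pairs of arrays was known, with its bounds set before its own value.

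Atf3 had a log2 ratio of −0.42 at 3 h, opposite in sign to 1.86 at 0.5 h and 2.26 at 1 h. The value at 3 h is short of 2-fold, and with 1 array per time the difference was not tested.

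Signals outside the gene comparisons also differed from the control array. Probe sets for poly-A control transcripts had a median log2 ratio of 0.41 at 3 h, after −0.05 at 0.5 h and 0.28 at 1 h, while those for hybridisation controls were at −0.07, 0.09 and 0.05. The 3 probe sets for 18S ribosomal RNA had medians of 0.96, 1.91 and 1.79 at 0.5, 1 and 3 h. The 5' minus 3' difference of Gapdh, Actb, Pcx and Tfrc was below the control at all 3 times, for example at −0.06, −0.16 and −0.16 for Gapdh and −0.41, −0.30 and −0.14 for Tfrc. Among probe sets without a single gene name, 15 were at least 2-fold higher at 1 h, with a median of 1.12 there, 0.00 at 0.5 h and 0.48 at 3 h, and 0 passed at the other times.

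The heat shock list was displaced upward at all 3 times. Scaling is argued against as the whole source at 0.5 h, since the list median of 0.23 stayed at 0.23 after centring, 0.23 after quantile scaling and 0.22 after loess, and the list lay at the 100th percentile of lists matched on signal, the observation that first marked the pattern. Signal shared between Hspa1a and Hspa1b is argued against as the whole source, because the other 15 members were also at the 100th percentile, with medians of 0.20, 0.39 and 0.29 at 0.5, 1 and 3 h. A less selective stress response is not settled. The median of 4 other stress lists was 0.209 of the heat shock median at 0.5 h, which met the bound set beforehand for setting it aside. That bound was stated for the ratio alone, and the bootstrap range over genes, from 0.00832 to 0.594, reached well past it. By the 2-fold rule, 0 of the 63 measured genes of those lists passed against 5 of 17 heat shock genes. LIPUS itself, warming of the culture during exposure and handling may each have raised these genes, and the design cannot separate them, since the labels describe no heated or sham-treated cells.

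Small shifts were shared by the 1 h and 3 h arrays. Noise of the control array is argued against as the whole source, because it enters only one side of contrasts that share no array, yet 1 h minus 0.5 h correlated with 3 h minus control with r = 0.432 across genes (0.445 without the genes past 2-fold), while 3 h minus 0.5 h with 1 h minus control gave 0.0800 (0.239 without them). Gene span had a Spearman's rho of 0.0769 with the 1 h ratios, which argues against long genes as a source. A difference in labelling or coverage that acts on single probe sets cannot be told apart from a change in transcript amount. Of the covariance of the first pair, over 4993 genes with 2 probe sets, 0.533 lay between probe sets of one gene. That share met the bound set beforehand for such a difference, at least 0.5. The bound was stated for the share alone, and the bootstrap range, from 0.496 to 0.572, began just under it. For 3 h minus 0.5 h with 1 h minus control the share was 0.656 (0.594 to 0.727), above the bound over its whole range. It was 0.219 for 1 h minus 3 h with 0.5 h minus control. Poly-A control transcripts, which do not come from the cells, split in the same way, with medians of −0.05, 0.28 and 0.41 at 0.5, 1 and 3 h. That goes with a technical part, but how much of the gene shifts it covers was not tested. Other controls were mixed. The 5' minus 3' difference of Gapdh, at −0.06, −0.16 and −0.16, set 1 h and 3 h apart from 0.5 h. That of Tfrc, at −0.41, −0.30 and −0.14, did not, and 18S ribosomal RNA was already at 0.96 at 0.5 h. A later response to LIPUS stays open as well, so the displaced medians of lists without a 2-fold member at 1 h and 3 h may be technical, biological or both.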

How the results depend on the processing

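The alternatives were fixed before the data were examined, except the LIPUS 3 h array as reference, which was added after seeing them. The fold threshold moved most counts, by construction. At 1.5-fold, 43, 109 and 40 genes were higher and 12, 38 and 21 lower at 0.5, 1 and 3 h, 52 differed between 0.5 h and 1 h and 54 between 1 h and 3 h, and the overlaps were 35 (0.5 h and 1 h), 8 (0.5 h and 3 h) and 23 (1 h and 3 h). At 3-fold, 10, 9 and 4 genes were higher, 0 differed between 0.5 h and 1 h, and the 1 h and 3 h overlap was 3. With the floor at the 75th percentile, which leaves dim genes with lower bounds or no ratio, 11, 13 and 5 genes were higher at 0.5, 1 and 3 h, and 2 and 5 genes differed between adjacent times. With the floor at the 25th percentile or none, 1 gene was lower at each time, H1f4, whose control signal of 4.84 is under the usual floor. Centring the arrays left 1 gene lower at 1 h, Ggcx. With quantile or loess scaling, 2 genes instead of 1 stood above all other arrays at 0.5 h, and the cause was not tested. Against the mean of the other 3 arrays, which includes treated cells, 9 genes were higher at 1 h, 1 was higher at 3 h and 6 were lower at 3 h. Against the 3 h array, 10 genes were higher at 1 h and 2 lower at 0.5 h. The TGF-beta list median at 1 h turned to 0.0278 with the floor at the 75th percentile and to 0.0228 with the mean over probe sets, and the cause was not tested. Of the other list medians under alternatives, 373 moved by less than the SD between probe sets and 3 by more. That SD describes the ratio of 1 gene and is larger than many list medians. A small median could therefore vanish and still count among the 373, and the percentiles were not recomputed. Of the named genes' ratios past 2-fold, 324 moved by less than that SD and 24 by more, of which 12 with the floor at the 75th percentile, and 0 reversed. Alternatives that left a gene without a ratio are not in this tally. They include Arc, Neat1, Hpgd and Krtap1-5 with the floor at the 75th percentile. Hspa1a and Fos likewise had no ratio when both arrays had to be above the floor. A pseudocount on linear values was not run, since the values are logarithmic. No paired analysis was possible because each group has 1 array, and no array could be left out within a group. Signal near the floor limits the folds of Hspa1a and Fos to lower bounds.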

Other observations

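The genes named below that lie short of 2-fold were chosen after their values were seen. The list of splicing regulators was drawn up after Clk1, Clk4 and Rsrp1 had been noticed, and the bounds of its test were set before its own result.

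Clock genes had ratios of both signs at 1 h. The repressor gene Nfil3 rose past 2-fold, with log2 ratios of 0.73, 1.14 and 0.39 at 0.5, 1 and 3 h, and Arntl, an activator of the clock, had log2 ratios of 0.30, 0.70 and 0.66. At 1 h the output gene Dbp was at −0.82, Cry2 at −0.81, Nr1d1 at −0.67 and Ciart at −0.60, each lower by more than 1.5-fold but short of 2-fold. The period genes Per1 and Per2, which respond early to serum and hormones in many cells, were at −0.38 and 0.03 at 0.5 h. The harvest time of the control cells was not stated in the labels.

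Against the control, no gene was 2-fold lower at any time with the arrays as deposited and the floor at the median. Genes lower by 1.5-fold numbered 12, 38 and 21 at 0.5, 1 and 3 h, where simulated unchanged arrays, with no spread between cultures, gave at most 9, 7 and 9. The simulated noise was pooled over times, so 7 is too low for the 1 h array, whose SD between probe sets was the largest. Ggcx, which encodes the vitamin K-dependent carboxylase, was among them at all times, at −0.69, −0.96 and −0.72, and it was just past 2-fold lower at 1 h when the arrays were centred. H1f4 was past 2-fold lower at all times with a lower floor or none. The nuclear noncoding RNA Malat1 was at −0.68 at 0.5 h and −0.73 at 1 h. The mitotic kinase genes Plk1 and Nek2 were at −0.66 and −0.73 at 1 h. At 3 h the lowest was Tnnt2 at −0.89. Of genes for secreted matrix proteins, Fmod was at 0.96 and 1.00 at 1 h and 3 h, just short of 2-fold at both.

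Clk1, Clk4 and Rsrp1, genes of splicing factor kinases and an arginine- and serine-rich protein, had log2 ratios of 1.29, 0.94 and 2.14 at 0.5 h and of 0.13, −0.03 and 0.38 at 3 h. A hypothesis is that they belong to a wider rise of splicing regulators. The other 26 measured regulators had a median of 0.05 at 0.5 h, at the 94.4th percentile of matched lists, with Luc7l highest at 0.50, and the percentile was 98.3 at 1 h and 14.9 at 3 h. The hypothesis asked for the 99th percentile or more at 0.5 h and would have been set aside under the 90th, so it stays undecided.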
